A study of Homo sapiens with 65 samples.

How the data were processed

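ChIP-seq libraries of G401 cells were grouped by mark, by construct or drug and by NSD1 status, each as the sample titles give them. Of 65 samples, 48 had a list of enriched regions, in 24 groups of 2, and 17 input samples were not used here. The title of 1 H3K27ac sample names GSK126 while its agent field names DMSO. It was grouped by title, and the other grouping was run as an alternative.

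Per the submitters' processing notes, the tools named include Trim Galore 0.6.3, BWA 0.7.17, SAMtools and bedtools, and the builds named are hg19, GRCh37 and dm6, with no role given. The aligner settings, the caller versions and whether reads were scaled to a spike-in are not given in the sources used here. Coordinates are hg19, which the chromosome ends in the lists fit. The 32 lists for H3K27me3 and H3K36me2 are islands and the 16 for H3K27ac are narrow peaks. The deposited names of the doxycycline experiment give SICER and MACS2 as callers, and the lists of the drug experiment have the same columns. Regions were called per library and not on pooled samples. Island starts lie on a 200 bp grid and islands are at least 800 bp apart. For the drug experiment the deposited file names give a window of 200 bp, a gap of 600 bp and an FDR of 0.00001, while all names of the doxycycline experiment carry the word filter, with its rule not given in the sources used here. Processing thus differed between the experiments, and levels were compared only within each.

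Each deposited island carries the counts of ChIP and of control reads inside it, which are raw and not scaled. Each deposited island also has a fold enrichment over control, a ratio scaled for library depth, a p-value and an FDR, none above 1e-05. Each deposited peak carries a score (10 times the −log10 q, as a whole number), a fold enrichment, −log10 p and −log10 q values, with the smallest −log10 q at 1.30, and a summit position. These values belong to the authors' caller and were used to rank regions within a list or to read off depth. An exception is the stricter island set for covered lengths, where 1 cutoff of raw reads per kb, not scaled for depth, was applied to all libraries of a mark. The ratio of ChIP to control depth was taken from islands with more than 20 control reads, where it was the same within each list to rounding (largest spread 6.59e-10 percent). Total read numbers are not in the lists, so the chance of missing an island in a shallow library is unknown, and no counting interval applies to a covered share.

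The genome (autosomes and X, 3036 Mb, 23 chromosomes) was divided into 303641 bins of 10 kb, and the percent of each bin covered by islands or peaks was computed per library. Bins replaced the gene promoters that the plan had put first, because no hg19 gene annotation was used here. The plan had named bins as the replacement. Bins covered by no library or fully by all 8 were left out, for each mark and experiment separately. Covered shares were fitted with limma 3.58.1 on the 8 libraries of a mark and experiment, with 4 group means, and Benjamini-Hochberg adjusted two-sided p under 0.05 was called. The contrasts were treatment within each NSD1 background and their difference. NSD1 loss averaged over treatments came from a second fit with treatment and NSD1 status. The contrasts of NSD1 loss within 1 treatment were added after seeing the data. Groups of a fit share 1 variance per bin, so the calls of both backgrounds are not independent and their overlap is raised by it. The overlap given for independent lists is the product of both list sizes over the bins tested in both. With 2 libraries per group, a library that stands apart moves many bins together.

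The rule for naming bins took the 5 of largest rise and of largest fall among those called, ties by position. Because many bins tied at a change of 100 points, the longest runs of adjacent called bins and the bands with most calls (of at least 100 tested bins) are also named, chosen after their values were seen. Cytobands came from circlize 0.4.16. Of 20052 protein-coding genes in the name table, 330 had an hg19 position in sample annotations of pyranges 0.1.4 and GenomicFeatures 1.54.1, and were read at the bin of their start site. This sample was added after seeing the data and was set by which positions were at hand, not by values. Of 409 genes in the 13 planned lists only GAPDH and MAP2 were among them, so the lists were not tested. Values for a called bin or run are from the libraries that called it and so lie at the high end. Levels of another mark at the same place, or of the other background, were not used to choose it.

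For windows of 1 kb, a mark was present where islands covered at least 50 percent, or where any H3K27ac peak lay, and lost or gained where both replicates of each group showed it. Covered lengths were compared as log2 ratios, and these and shares of windows were tested by exact permutation within backgrounds, two-sided. Standard errors of window shares came from leaving out each chromosome in turn. Overlaps of falls used Fisher's exact test.

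Whether libraries of the same replicate number deviate together was checked by correlating the difference between replicates over bins for each of the 6 pairs of groups. In the drug experiment every correlation was above 0.1 for H3K27me3 (0.122 to 0.485) and H3K36me2 (0.166 to 0.553), which was taken as pairing from the data, since the labels do not state any. Not every correlation was above 0.1 for H3K27ac or in the doxycycline experiment. For H3K27ac some groups still deviated together, with correlations up to 0.813 in the drug and 0.361 in the doxycycline experiment.

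The tests, groups and alternatives were fixed before the data were examined, except where stated. The alternatives were bins of 5 kb, a stricter island set (the densest 75 percent of the covered length in reads per kb or, for covered lengths, islands above the lower quartile of density over the libraries of a mark, 40.9 reads per kb for H3K27me3 and 40.8 for H3K36me2), every library trimmed in the same order, or by −log10 q for peaks, to the covered length of the smallest library of its mark and experiment, islands of at least 2 kb, bins with a mean share between 0.1 and 0.9, a variance trend in limma, the replicate number as a block, windows of 5 kb or 10 percent covered, the other grouping of the H3K27ac sample, and leaving out each library. The smallest covered lengths were 461 and 341 Mb for H3K27me3 and H3K36me2 and 39.3 Mb for H3K27ac in the doxycycline experiment, and 48.1, 656 and 26.1 Mb in the drug experiment. Trimming removes any difference in total coverage, technical or real, and the overlap of calls under it was added after seeing the data, as was the count of named regions and genes it still called.

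The fit was tested on simulated data with 1000 bins each seeded with a change of 25, 50 or 75 points. The 2 libraries of a group were set equally far above and below 1 mean shared by all groups. That distance came from the real replicate differences of bins of like mean. Its sign was drawn at random per bin, so shifts of a whole library were not simulated. Simulated shares were held between no and full coverage, so many bins of intermediate mean share changed by less than the nominal 75 points. In the doxycycline experiment the fit recovered 2.7, 12.2 and 29.2% of the seeded bins for H3K27me3. It recovered 0.9, 8.2 and 17.6% for H3K36me2 and 1.1, 8.6 and 21.5% for H3K27ac. False calls were 0%, but unseeded bins had equal group means by construction, apart from the limits on shares. The simulation therefore does not measure the rate of false calls. In the drug experiment the fit recovered at most 1.1%, for H3K36me2, and 0% for the other marks. A low count of calls therefore sets no upper limit on change. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and GenomeInfoDb 1.38.1.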

Results

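Histone marks were mapped by ChIP-seq in G401, an established human cell line from a malignant rhabdoid tumour that lacks SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex. The 3 marks were H3K27me3, the repressive mark made by EZH2, H3K36me2, which NSD1 and related enzymes make, and H3K27ac, a mark of active promoters and enhancers. In the doxycycline experiment, cells with a control guide (sgControl) or a guide against NSD1 (sgNSD1) expressed GFP or SMARCB1 after 24 h in 1 µg/mL doxycycline. Replicates were numbered 1 and 2, except for H3K27ac in SMARCB1 sgControl cells, numbered 1A and 2, where 1A was counted as 1. In the drug experiment, cells with a control hairpin (shControl) or an NSD1 hairpin (shNSD1) received DMSO or 1 µM of the EZH2 inhibitor GSK126 for 72 h, with replicates numbered 6 and 7. The 48 libraries formed 24 groups of 2. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are the percent of a region covered by the islands (H3K27me3, H3K36me2) or peaks (H3K27ac) called in each library, as mean ± SD over 2 libraries unless another n is given. A level of 0 says only that no island was called there.

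Island and peak numbers ran from 8629 to 122271 per library. H3K27me3 islands of the doxycycline experiment covered 564 ± 25.5 Mb in GFP sgControl, 470 ± 12.9 Mb in SMARCB1 sgControl, 539 ± 18.8 Mb in GFP sgNSD1 and 604 ± 21.4 Mb in SMARCB1 sgNSD1 cells (n = 2 each). H3K36me2 islands covered 731 ± 63.4, 756 ± 60.5, 722 ± 5.10 and 461 ± 170 Mb in the same order, and H3K27ac peaks 124 ± 8.36, 157 ± 2.49, 135 ± 20.4 and 95.5 ± 79.5 Mb. In the drug experiment H3K27me3 islands covered 640 ± 38.8 Mb with DMSO and 304 ± 361 Mb with GSK126 in shControl cells, and 587 ± 102 and 514 ± 0.271 Mb in shNSD1 cells. Reads inside islands, in megareads, ran from 25.5 to 44.0 per H3K27me3 library and from 18.2 to 61.8 per H3K36me2 library in the doxycycline experiment. The drug experiment had 2.54 to 40.2 and 28.9 to 55.3 megareads. Total reads per library are not given in the lists, so the depth behind an absent island is known only from the ratio of ChIP to control reads, which ran from 0.839 to 2.58. Levels were not compared across the experiments, whose lists were processed differently.

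**Figure D1:**
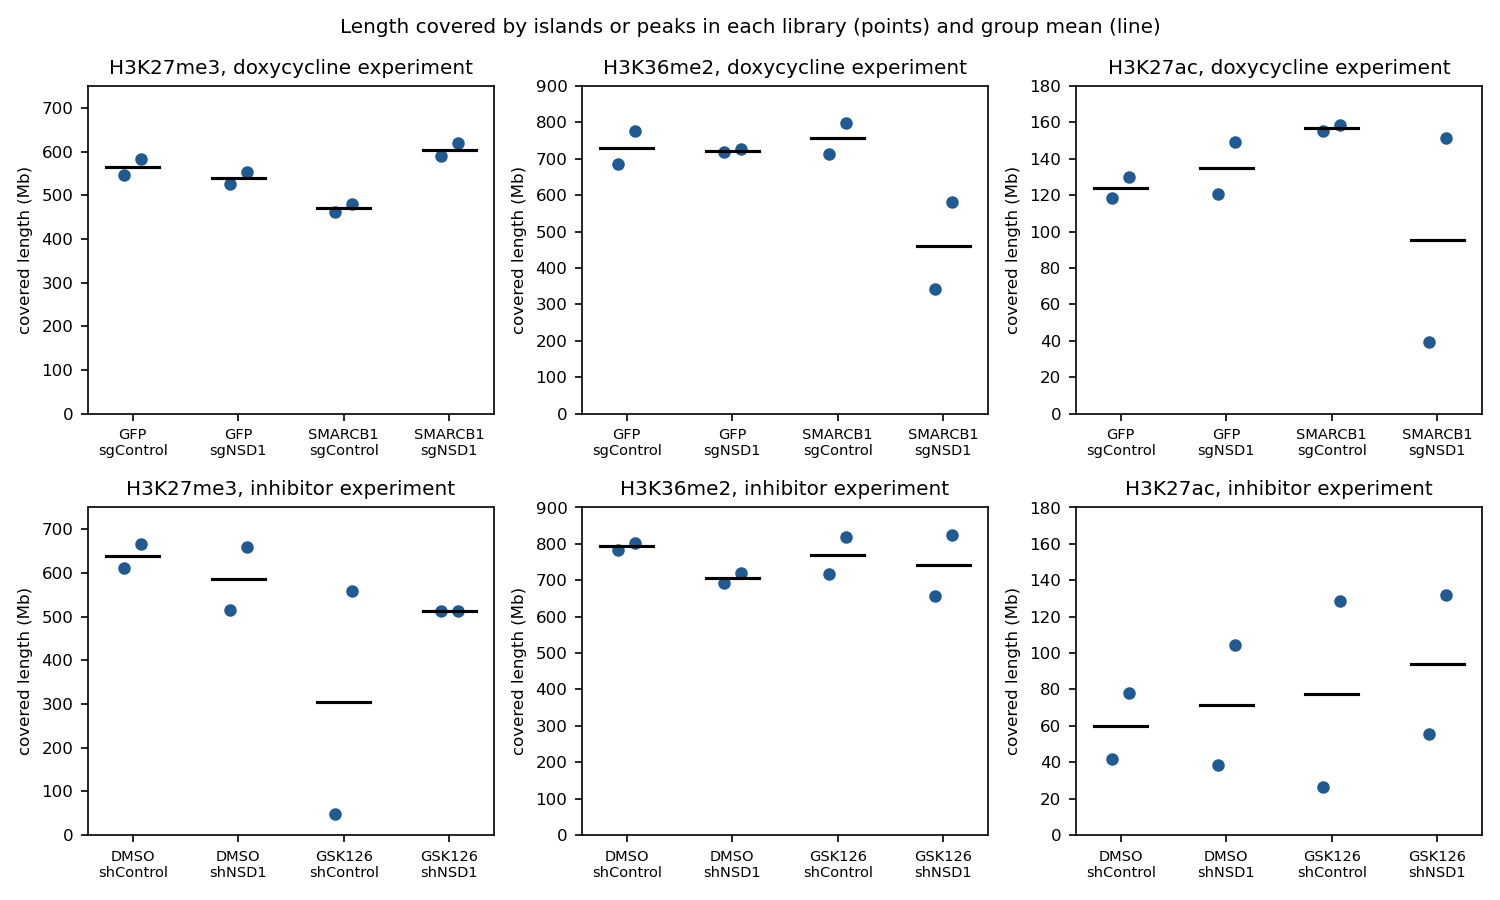
Length of the genome covered by islands or peaks (Mb, vertical axis) in each of the 48 libraries, by mark and group; points are libraries and horizontal lines are group means. GSK126 shControl replicate 6 stands apart at 48.1 Mb of H3K27me3, against 559 Mb in replicate 7.

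To find where H3K27me3 depended on SMARCB1, GFP and SMARCB1 cells with the control guide were compared. Long H3K27me3 domains were lost. At 6p21.1 (chr6:45400001-45610000, hg19), 210 kb fell from 89.0 ± 2.29% covered to 0.667 ± 0.808%, and at 2p24.1 (chr2:23570001-23800000) 230 kb fell from 87.2 ± 3.87% to 6.17 ± 0.123% (n = 2). Domains were also gained: at 10q26.3 (chr10:132780001-133080000), 300 kb without an island in GFP cells were 85.4 ± 0.943% covered with SMARCB1. In that band 133 of the 301 tested 10-kb bins rose (44.2%), against 2.36% of bins genome-wide, while 8p11.21 lost the mark in 75 of 168 bins and 18q11.2 in 102 of 261. Genome-wide, 8713 of 107830 tested bins fell and 2547 rose (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05). Among bins that changed by 100 points (77 risen and 211 fallen), the first by position rose at 1q32.2, 1q42.13 and 3 times at 2q24.2 and fell at 1p31.3, 1p21.3, 1p13.2 and 1q25.2. Of 330 protein-coding genes whose hg19 position was known, 106 had a tested start-site bin, of which 6 fell and 5 rose. The falls included SEPTIN10, a septin, at 2q13 (96.0 ± 5.66% to 0, limma adjusted p = 0.000262), TSHZ1, a zinc-finger homeobox factor, at 18q22.3 (82.0 ± 11.3% to 0, adjusted p = 0.00132), IDO2, a tryptophan-degrading dioxygenase, and PDE4D, a cAMP phosphodiesterase. SH3KBP1, an endocytic adaptor gene at Xp22.12, rose from 0 to 55.0 ± 1.41% (limma adjusted p = 0.000916), and AGXT, alanine-glyoxylate aminotransferase, at 2q37.3 rose from 36 ± 5.66% to 78.0 ± 5.66%. With each library trimmed to the same covered length, the excess of falls was gone, with 4226 bins risen and 4122 fallen, while limma still called 18 of the 20 testable bins at 6p21.1, 20 of 23 at 2p24.1, all 30 at 10q26.3 and SEPTIN10, TSHZ1 and AGXT, but not IDO2 or SH3KBP1, and PDE4D held no island to test. Without SMARCB1 sgControl replicate 2 the counts were 2260 risen and 5037 fallen.

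In sgNSD1 cells SMARCB1 removed H3K27me3 from some of the same domains. At 6q23.3 (chr6:138440001-138680000), 240 kb fell from 87.8 ± 1.77% to 0, and at 7q34 (chr7:141030001-141230000) 200 kb fell from 86.6 ± 2.40% to 0 (n = 2). In sgControl cells the mark covered 78.3 ± 5.19% of the 6q23.3 and 87.1 ± 1.27% of the 7q34 region in GFP and 0 of both in SMARCB1 cells. The 10q26.3 domain rose here too, to 85.1 ± 1.32%, with 136 of 301 bins of the band risen. SEPTIN10 fell from 100% to 2 ± 2.83% and TSHZ1 to 0. CCDC197, at 14q32.12, rose from 0 to 95.0 ± 7.07%, ECE2, an endothelin-converting enzyme, to 56.0 ± 5.66% and CDA, cytidine deaminase, to 47.0 ± 7.07%, making 9 rises and 7 falls among the 106 tested genes. Over the genome the balance went the other way from sgControl cells, with 7321 bins risen and 4180 fallen by limma. The mean change over tested bins was 6.01 points, against -8.74 points in sgControl cells. Both lists shared 1498 risen bins, against 173 for independent lists of these sizes, and 2795 fallen bins, against 338. The test of the difference between the 2 backgrounds called 4313 bins with a more positive and 653 with a more negative change in sgNSD1 cells. Trimmed to equal length, SMARCB1 in sgNSD1 cells gave 3844 risen and 4498 fallen bins and the difference 1534 and 1996, so the direction of both turned, while both lists still shared 1490 risen and 2064 fallen bins. Limma then called 20 of the 24 bins at 6q23.3, all 20 at 7q34, all 30 at 10q26.3 and CCDC197, SEPTIN10 and TSHZ1, but not CDA, and ECE2 could not be tested. The difference also moved without GFP sgControl replicate 1 (7791 more positive, 1179 more negative), SMARCB1 sgControl replicate 2 (2252 and 493), SMARCB1 sgNSD1 replicate 1 (8199 and 1187) or SMARCB1 sgNSD1 replicate 2 (10837 and 1482).

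**Figure D2:**
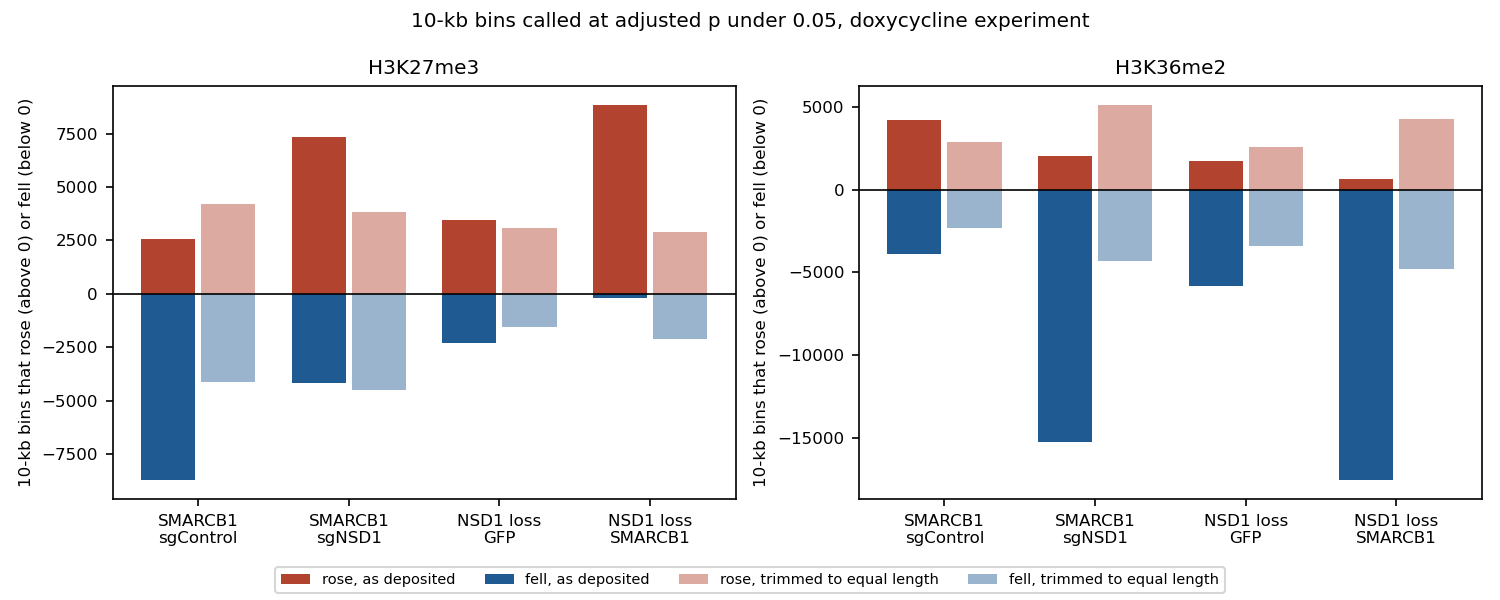
Number of 10-kb bins that rose (above 0) or fell (below 0) at a limma adjusted p under 0.05 for each comparison of the doxycycline experiment, with islands as deposited (dark bars) and with every library trimmed to equal covered length (light bars). For H3K27me3 with SMARCB1 in sgControl cells the bars change from 2547 risen and 8713 fallen to 4226 and 4122.

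H3K36me2 was next compared between GFP and SMARCB1 cells. In sgControl cells the longest gain was at 10p13 (chr10:12420001-12890000), where 470 kb rose from 0.234 ± 0.271% to 98.9 ± 0.331% covered, followed by 300 kb at 7q34 (chr7:140840001-141140000), from 0 to 98.4 ± 0.943%. The longest loss was 430 kb at 8q24.22 (chr8:132250001-132680000), from 91.6 ± 1.84% to 0, followed by 410 kb at 8p23.3 (chr8:930001-1340000), from 91.7 ± 0.0345% to 0. The band 9q21.32 gained the mark in 81 of 157 tested bins and 8q24.22 lost it in 110 of 206. SGCE, epsilon-sarcoglycan, rose from 11 ± 7.07% to 100% and SEPTIN10 from 0 to 82.0%, while AGXT fell from 96.0 ± 5.66% to 0 (limma adjusted p = 0.000352), with 5 rises and 6 falls among 247 tested genes. Of the bins that changed by 100 points, the first by position rose at 1p36.21 and 4 times at 1p33, and fell 5 times at 1p36.13. Genome-wide, limma called 4201 risen and 3872 fallen bins of 111749, and 2894 and 2315 at equal covered length. There it still called all 47 bins at 10p13, 14 of 30 at 7q34, 28 of 43 at 8q24.22, 36 of 41 at 8p23.3, 1 of the 5 risen genes (SEPTIN10, not SGCE) and 1 of the 3 fallen genes that could be tested (CCDC197). AGXT and 2 other fallen genes held no island in any trimmed library and could not be tested. PRPF39, a splicing factor gene at 14q21.2, called as a rise (31 ± 1.41% to 78.0 ± 8.49%), was called as a fall there (limma adjusted p = 0.00288). This near-even balance turned to an excess of falls without any of 5 libraries: GFP sgControl replicate 1 (2416 risen, 5040 fallen) or 2 (3061, 3922), GFP sgNSD1 replicate 1 (2623, 2997) or 2 (2623, 2999), or SMARCB1 sgControl replicate 1 (3128, 3703).

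In sgNSD1 cells losses of H3K36me2 prevailed with SMARCB1. The 8q24.22 loss spanned 780 kb (chr8:132060001-132840000), from 92.8 ± 0.508% to 1.00 ± 1.41%, and 510 kb at 18q23 (chr18:74910001-75420000) fell from 91.5 ± 0.499% to 1.78 ± 0.305%. The 10p13 gain was also present, over 560 kb (chr10:12320001-12880000). Of the tested genes, 43 fell and 1, FGD3, a guanine-nucleotide exchange factor gene, rose from 0 to 30.0 ± 14.1%. The falls included CCDC197 (100% to 0, limma adjusted p = 0.000247), CDA (100% to 0) and HGF, hepatocyte growth factor (96.0 ± 5.66% to 11 ± 15.6%). Limma called 2002 risen and 15287 fallen bins, and the difference from sgControl cells was more negative in 6064 and more positive in 1213 bins. Fallen bins of both backgrounds overlapped in 2041, against 530 for independent lists, and risen bins in 1325, against 75.3. These counts rested on SMARCB1 sgNSD1 libraries that covered 341 and 582 Mb. At equal covered length sgNSD1 cells gave 5129 risen and 4330 fallen bins and the difference 3499 more positive and 3074 more negative, so the direction turned, with 749 fallen bins still shared, against 124. Limma then called 60 of the 77 testable bins at 8q24.22, 30 of 45 at 18q23 and 55 of 56 at 10p13. Of the 43 fallen genes 34 could be tested and 3 were called, CCDC197 and CDA included, while HGF could not be tested. The fall and the difference also moved without GFP sgNSD1 replicate 1 (1062 risen and 7360 fallen; difference 620 and 3090), GFP sgNSD1 replicate 2 (1091 and 7721; 692 and 3443) or SMARCB1 sgNSD1 replicate 1 (4523 and 52429; 3924 and 49419), and the difference without SMARCB1 sgNSD1 replicate 2 (2628 and 16418).

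H3K27me3 and H3K36me2 were then set side by side. In the 6p21.1 domain that lost H3K27me3, H3K36me2 covered 0 in GFP and 98.9 ± 1.01% in SMARCB1 sgControl cells, and at 2p24.1 17.4 ± 2.95% and 94.9 ± 2.03%. In the 10p13 region that gained H3K36me2, H3K27me3 covered 75.9 ± 0.782% in GFP and 0 in SMARCB1 cells, and in sgNSD1 cells 70.5 ± 2.02% and 0. The 8q24.22 region that lost H3K36me2 had little H3K27me3 afterwards in sgControl cells (3.49 ± 0.526%) and 24.6 ± 6.85% over its longer span in sgNSD1 cells. Over all 8713 bins that lost H3K27me3 in sgControl cells, H3K36me2 averaged 4.55 ± 0.650% in GFP and 20.6 ± 1.24% in SMARCB1 cells. Over the 2547 that gained it, H3K36me2 averaged 38.0 ± 3.82% and 16.2 ± 1.45%. Among the 27570 bins tested for both marks, 1166 lost H3K27me3 and gained H3K36me2, against 237 for independent lists, and 539 did the reverse, against 153. Bins in which both marks rose numbered 13, against 140, and bins in which both fell 26, against 259. At equal covered length the opposite-direction overlaps were 360, against 90.6, and 159, against 51.9. At 74342 windows of 1 kb that lost H3K27me3 in both replicates, H3K36me2 marked 3.77 ± 0.401% in GFP and 17.9 ± 0.990% in SMARCB1 sgControl cells and 1.90 ± 0.0447% and 10.6 ± 2.99% in sgNSD1 cells. The mean rise over the 2 backgrounds was 11.4 points (exact permutation test, two-sided p = 0.0556, the smallest that 36 arrangements allow, n = 2 per group). Over all windows of the genome H3K36me2 marked 24.1 and 24.9% in sgControl and 23.8 and 15.2% in sgNSD1 cells. H3K27ac peaks lay in 0.923 ± 0.104% and 3.47 ± 0.0561% of the windows that lost H3K27me3 in sgControl cells and in 0.938 ± 0% and 2.20 ± 1.75% in sgNSD1 cells. The mean rise was 1.91 points (exact permutation test, two-sided p = 0.0556; difference between backgrounds p = 0.556). Over all windows the shares were 6.02 and 7.68%, and 6.48 and 4.98%. SMARCB1 sgNSD1 replicate 1 stood at 0.959% of the windows that lost H3K27me3 and replicate 2 at 3.44%, so replicate 2 carried the rise of this share in sgNSD1 cells. Over all windows replicate 1 had peaks in only 2.35% and replicate 2 in 7.62%, against 5.88 and 7.08% in the GFP sgNSD1 libraries. The share of replicate 1 at windows that lost H3K27me3 thus did not fall along with its share of all windows. Its missing rise cannot be told from its low number of peaks.

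**Figure D3:**
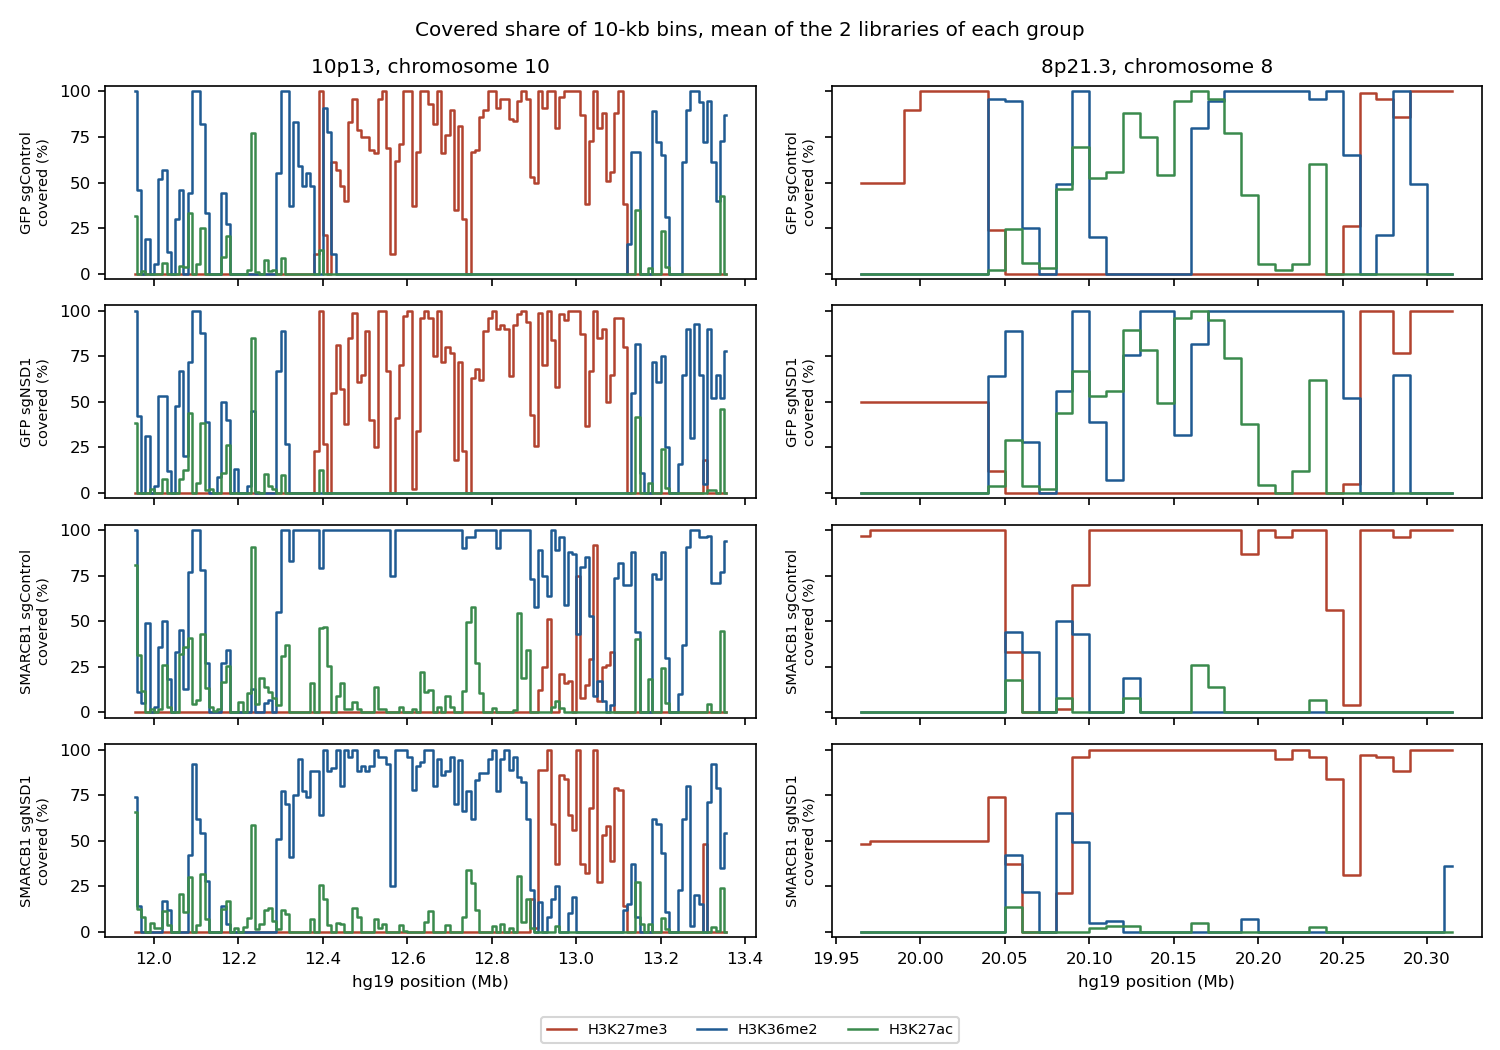
Percent of each 10-kb bin covered (vertical axis) against hg19 position in Mb (horizontal axis) at 10p13 and 8p21.3 in the 4 groups of the doxycycline experiment, with lines for the mean of 2 libraries of H3K27me3, H3K36me2 and H3K27ac. With SMARCB1 the 10p13 region changes from H3K27me3 (75.9%) to H3K36me2 (98.9%), and 8p21.3 from H3K27ac (78.5%) to H3K27me3 (98.4%).

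H3K27ac with SMARCB1 fell over some long active regions, although in sgControl cells peaks covered more in total, 157 ± 2.49 Mb against 124 ± 8.36 Mb with GFP. At 10q21.1 (chr10:54350001-54450000), 100 kb fell from 90.8 ± 5.10% to 0 in sgControl and from 94.0 ± 3.12% to 0 in sgNSD1 cells (n = 2). At 8p21.3 (chr8:20120001-20200000), 80 kb fell from 78.5 ± 5.57% to 5.94 ± 1.48%, where H3K27me3 covered 0 in GFP and 98.4 ± 0.884% in SMARCB1 cells, and H3K36me2 46.9 ± 0.884% and 2.38 ± 3.36%. Single bins at 8q24.22 (chr8:132830001-132840000) and 12q23.3 (chr12:107510001-107520000) fell from 100% to 0 in both backgrounds, and the rises in sgControl cells were led by 5q13.2 (chr5:71580001-71590000, 2.70 ± 3.82% to 68.4 ± 7.62%), 3q12.1 (chr3:99660001-99670000, 0 to 65.3 ± 4.84%), 1q32.1, 1q43 and 10q24.32. Of 247 tested genes, CCDC197 fell from 74.9 ± 8.28% to 1.90 ± 2.68% (limma adjusted p = 0.0116) and NFIA, a nuclear factor I transcription factor, from 42.6 ± 2.88% to 5.21 ± 7.37% (adjusted p = 0.0342), and both fell in sgNSD1 cells. GAPDH, a housekeeping enzyme, was at 94.9 ± 4.87% and 93.3 ± 4.43% in sgControl cells. In sgNSD1 cells it was at 92.9 ± 3.05% with GFP and 68.4 ± 40.0% with SMARCB1, not called (limma adjusted p = 0.589). The 2 SMARCB1 sgNSD1 libraries thus differed widely even there. Limma called 64 risen and 351 fallen bins of 69602 in sgControl cells. In sgNSD1 cells it called 0 risen and 785 fallen bins, with 8698 bins at an unadjusted p under 0.05, and 342 of the falls were shared, against 3.96. The difference between backgrounds gave 0 calls by limma (3098 bins at an unadjusted p under 0.05). The falls in sgControl cells overlapped with gains of H3K27me3 in 69 bins, against 12.6. Each of the 8 libraries moved these counts, and the excess of falls was not stable. The SMARCB1 sgNSD1 libraries, at 39.3 and 152 Mb, do not enter the sgControl means. They act on the sgControl calls through the variance that all groups share and through which bins are tested. In sgControl cells the mean change was above 0 on all 23 chromosomes, so the excess of called falls does not give the direction of H3K27ac there. In sgControl cells rises outnumbered falls without SMARCB1 sgControl replicate 1A or without either SMARCB1 sgNSD1 library. In sgNSD1 cells they did so without SMARCB1 sgNSD1 replicate 1. In sgControl cells they were 1 risen and 138 fallen without GFP sgControl replicate 1, 0 and 79 without its replicate 2, 13 and 241 without GFP sgNSD1 replicate 1, 6 and 225 without its replicate 2, 1463 and 268 without SMARCB1 sgControl replicate 1A, 98 and 108 without its replicate 2, and 6808 and 1488 or 6835 and 1521 without SMARCB1 sgNSD1 replicate 1 or 2. In sgNSD1 cells they were 0 and 312, 0 and 320, 0 and 413, 0 and 161, 1 and 224, 0 and 215, 5499 and 1610, and 552 and 12812 in the same order, and the difference gave 0 and 531 without SMARCB1 sgControl replicate 1A and 136 and 13874 without SMARCB1 sgNSD1 replicate 2. SMARCB1 sgNSD1 replicate 1 covered only 39.3 Mb, and at that length in every library limma called 77 risen and 141 fallen bins in sgControl and 47 and 130 in sgNSD1 cells. It then called 1 of the 4 testable bins at 8p21.3 and not 3q12.1 or NFIA, while 10q21.1, the other single bins and CCDC197 held no peak to test.

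The effect of NSD1 loss itself was tested over GFP and SMARCB1 cells together (n = 4 per side). H3K36me2 fell at 1p36.12 (chr1:23160001-23300000), where 140 kb changed from 74.8 ± 5.93% to 2.36 ± 2.30%, and at 12p13.31 (chr12:7790001-7900000), from 77.2 ± 13.2% to 8.18 ± 3.29%. Single bins at 1p36.11, 2p23.3, 2p11.2 and 2q11.2 fell from 100% in all 4 control libraries to 0. Of 247 tested genes, 14 fell and 0 rose by limma, among them MLKL, the necroptosis effector (96.0 ± 4.90% to 14.0 ± 9.66%, adjusted p = 0.000982), NGFR, the low-affinity neurotrophin receptor (69.5 ± 3.42% to 22.0 ± 2.31%), AMPD3, an AMP deaminase (90.5 ± 11% to 22.5 ± 19.1%), SFTPC, surfactant protein C (65.0% to 0), and IL6ST, the gp130 receptor subunit (82.5% to 41.5%). Limma called 6520 fallen and 283 risen bins, with 62 of the 278 tested bins of 1p36.12 among the falls. All 23 chromosomes had a negative mean change in this average and in SMARCB1 cells alone, but only 17 in GFP cells, with 6 above 0 (X highest). In GFP cells alone 5851 bins fell and 1717 rose, and in SMARCB1 cells alone 17585 fell and 638 rose. At equal covered length the averaged test called 2310 fallen and 1059 risen bins, with NGFR the 1 gene of the 14 and 1 of the 11 testable bins at 1p36.12 still called. At 12p13.31 3 of 11 bins could be tested and 0 were called by limma, and of the single bins those at 2p11.2 and 2q11.2 and 1 of the 2 at 2p23.3 could not be tested and the others were not called. It gave 4237 fallen and 158 risen bins without GFP sgControl replicate 2 and 4166 and 186 without SMARCB1 sgControl replicate 1. In GFP cells the counts were 3136 fallen and 1467 risen without GFP sgNSD1 replicate 1 and 3267 and 1573 without its replicate 2, and in SMARCB1 cells 9153 and 422 without SMARCB1 sgControl replicate 1 and 57245 and 2424 without SMARCB1 sgNSD1 replicate 1. At equal length GFP cells gave 3414 fallen and 2579 risen bins and SMARCB1 cells 4796 and 4289.

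H3K27me3 was tested over the same cells, and nearly all called bins rose. At 1p34.3 to 1p34.2 (chr1:40080001-40160000), 80 kb rose from 6.25 ± 1.17% to 50.5 ± 8.10%, and at 6p21.31 (chr6:33850001-33920000) 70 kb from 1.14 ± 2.29% to 75.7 ± 11.5% (n = 4). H3K36me2 over the 6p21.31 region covered 98.9 ± 1.62% in GFP sgControl and 51.4 ± 7.27% in GFP sgNSD1 cells, and 99.1 ± 1.21% and 46.3 ± 3.64% in SMARCB1 cells. At 2q14.2 (chr2:121850001-121870000) H3K27me3 fell from 77.8 ± 6.65% to 4 ± 5.23%. Single bins at 5q32, 6p21.31 and 8q24.13 rose from 0 to 100% (limma adjusted p = 9.41e-05). Of 106 tested genes 13 rose and 0 fell by limma: DMTN, the actin-binding protein dematin (0 to 78.0 ± 2.83%, adjusted p = 0.000194), NGFR (47.5 ± 6.61% to 100%), ATP1B1, a subunit of the sodium-potassium pump (0 to 44.5 ± 9.85%), KLHDC9 (0 to 53.5 ± 13.9%), ANK2, an ankyrin (8.00 ± 9.38% to 58.0 ± 7.83%), NTSR1, the neurotensin receptor (59.0% to 96.5%), and 7 more. NGFR, KLHDC9 and PLCH2 were called for both marks. Limma called 3385 risen and 69 fallen bins, and 1568 and 362 at equal covered length, where 2 of the 8 bins at 1p34.3 to 1p34.2, 6 of 7 at 6p21.31, both at 2q14.2 and 7 of the 13 genes were still called, DMTN, NGFR, ATP1B1 and NTSR1 included and KLHDC9 and ANK2 not. Without SMARCB1 sgControl replicate 1 they were 2021 and 48. In SMARCB1 cells alone 8844 bins rose and 191 fell, moving to 5216 and 446 without SMARCB1 sgControl replicate 2, to 12905 and 777 without SMARCB1 sgNSD1 replicate 2 and to 2914 and 2089 at equal length. The mean change was below 0 on 15 of the 23 chromosomes in GFP cells, where covered length was 564 ± 25.5 Mb before and 539 ± 18.8 Mb after NSD1 loss, and above 0 on all 23 in SMARCB1 cells. In GFP cells 3464 rose and 2310 fell, a direction that turned without GFP sgControl replicate 1 (3176 and 5277) or 2 (3097 and 3365), while equal length gave 3091 and 1561. In the 6520 bins that lost H3K36me2, H3K27me3 averaged 11.5 ± 0.610% in GFP sgControl and 30.2 ± 0.310% in GFP sgNSD1 cells, and 11.5 ± 0.747% and 39.8 ± 3.63% in SMARCB1 cells (n = 2 each). Loss of H3K36me2 coincided with gain of H3K27me3 in 1501 of 27570 bins tested for both marks, against 559 for independent lists, and in 187, against 72.4, at equal length.

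Windows of 1 kb gave a closer view of where the marks exchanged. In GFP cells 14.8% of 54307 windows that lost H3K36me2 in both replicates with NSD1 loss gained H3K27me3 in both, against 0.657% of 560165 windows that kept H3K36me2. The shares were 8.99% of 148409 and 1.14% of 291749 in SMARCB1 cells, 7.60% of 45518 and 0.304% in DMSO cells, and 17.1% of 29238 and 1.21% in GSK126 cells. The differences between lost and kept windows were 14.1, 7.85, 7.29 and 15.9 points, with standard errors over the 23 chromosomes of 0.813, 0.637, 0.434 and 0.829 points, which do not cover the spread between libraries. Kept windows held H3K36me2 in every library of both groups, and both marks rarely rose in the same bins with SMARCB1. The low share of gains in kept windows may thus partly follow from how they were chosen. The difference between lost and kept windows was above 0 without each single library, yet its size moved. In SMARCB1 cells it was 2.39 points without the H3K36me2 library of SMARCB1 sgNSD1 replicate 1. In DMSO cells it was 16.7 and 26.8 points without the H3K27me3 libraries of shControl replicate 6 and shNSD1 replicate 7, and 4.10 and 3.32 points without the H3K36me2 libraries of replicate 6 of shControl and shNSD1. In GSK126 cells it was 36.1 and 25.7 points without the H3K27me3 libraries of replicate 7 of shControl and shNSD1, and 10.5, 10.6 and 9.89 points without the H3K36me2 libraries of shControl replicate 6, shControl replicate 7 and shNSD1 replicate 7.

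GSK126 was compared with DMSO to see which H3K27me3 domains EZH2 inhibition removed and whether other marks changed there. H3K27me3 in shControl cells covered 48.1 Mb with GSK126 and 667 Mb with DMSO in replicate 6, but 559 and 612 Mb in replicate 7. In shNSD1 cells it covered 514 and 658 Mb in replicate 6, and 514 and 515 Mb in replicate 7. The mean log2 ratio of covered length was -1.07 over both backgrounds (exact permutation test, two-sided p = 0.0556, the smallest that 36 arrangements allow, n = 2 per group), but -0.19 without GSK126 shControl replicate 6 and -1.96 without its replicate 7. Exchanging treatments only within replicate numbers gave p = 0.125 (exact permutation, the smallest that 16 arrangements allow). At bin level limma called 0 of 114657 bins in shControl cells (8854 at an unadjusted p under 0.05, mean change -29.3 points), 0 in shNSD1 cells (803 unadjusted, mean -6.35 points) and 0 for their difference (2048 unadjusted). Single libraries moved the shControl result and the difference: without GSK126 shControl replicate 7, 49616 bins fell and 63 rose in shControl cells and the difference was more positive in 37291 bins and more negative in 125, and without DMSO shControl replicate 7, 623 fell and 0 rose. At equal covered length, 48.1 Mb per library, limma called 50 risen and 168 fallen bins in shControl, 112 and 75 in shNSD1 cells and 149 and 45 for the difference. Fitted to simulated changes of nominally 75 points (many smaller, since shares cannot pass full coverage) at the spread of these libraries, limma recovered 0% of H3K27me3 bins. The counts of 0 therefore set no limit on the change. At the 61190 windows that lost H3K27me3 in both shControl replicates, H3K36me2 marked 6.54 ± 1.95% with DMSO and 10.2 ± 2.91% with GSK126, and 2.04 ± 1.27% and 4.59 ± 2.66% in shNSD1 cells, a mean difference of 3.12 points (exact permutation test, two-sided p = 0.111; difference between backgrounds p = 0.778). Within replicate numbers it was higher with GSK126 in all 4 pairs, by 3.01 and 4.37 points in shControl and 1.57 and 3.53 points in shNSD1 cells (exact permutation within pairs, two-sided p = 0.125, the smallest that 16 arrangements allow). Over all windows H3K36me2 marked 26.1 and 25.3% in shControl and 23.3 and 24.4% in shNSD1 cells. H3K27ac marked 0.719 ± 0.233% and 0.928 ± 0.573% of them, and 0.909 ± 0.471% and 1.2 ± 0.730% in shNSD1 cells, a mean difference of 0.248 points (exact permutation p = 0.500). Over all windows the mean share with H3K27ac was also higher with GSK126, at 3.33 and 4.28% in shControl and 3.79 and 5.35% in shNSD1 cells, a difference not particular to the windows that lost H3K27me3. In shControl cells this rested on replicate 7 (2.17% with DMSO, 6.63% with GSK126), while replicate 6 fell from 4.48 to 1.92%. The difference at windows that lost H3K27me3 turned to -0.00981 points without GSK126 shNSD1 replicate 7. It turned to -0.0567 points with the H3K27ac library of GSK126 shControl replicate 7 counted as DMSO, as its agent label says.

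H3K36me2 and H3K27ac with GSK126 gave no limma call over the genome. For H3K36me2 limma called 0 bins in shControl cells (3867 at an unadjusted p under 0.05), 0 in shNSD1 cells (3102) and 0 for the difference (3236), and at equal covered length 207 risen and 76 fallen, 25 and 58, and 23 and 37 bins. Without GSK126 shControl replicate 6, 2100 bins rose and 212 fell in shControl cells, and the difference was more positive in 75 and more negative in 1061. Without GSK126 shControl replicate 7 these counts were 1284 and 855, and 169 and 488. In shNSD1 cells they were 115 and 1 without GSK126 shNSD1 replicate 6 and 1693 and 866 without DMSO shNSD1 replicate 7, which also gave 691 and 487 for the difference. For H3K27ac limma called 0 bins in shControl cells (39 at an unadjusted p under 0.05), 0 in shNSD1 cells (1166) and 0 for the difference (269). Without GSK126 shControl replicate 6, 1075 bins rose and 0 fell in shControl cells and the difference was more negative in 207. Without GSK126 shNSD1 replicate 6, 8016 rose and 9 fell in shNSD1 cells and the difference was more positive in 3022 and more negative in 2. The H3K27ac library titled GSK126 shControl replicate 7 has DMSO as its agent in the labels and was grouped by its title.

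NSD1 knockdown in the drug experiment was tested over DMSO and GSK126 cells together (n = 4 per side). H3K36me2 fell at 1q42.2 (chr1:231830001-232020000), where 190 kb went from 83.8 ± 7.70% to 1.79 ± 1.25%, and at 1q42.3 (chr1:236510001-236580000), from 84.6 ± 5.00% to 4.50 ± 5.41%. It rose at 6q24.1 (chr6:140410001-140440000), from 3.50 ± 7% to 83.7 ± 9.26%. GUCA2B, the gene of uroguanylin at 1p34.2, fell from 53.5 ± 12.2% to 8.50 ± 5.74% (limma adjusted p = 0.0431), the 1 call among 248 tested genes. Single bins at 2q11.2, 6p23, 9p22.3, 10p11.23 and 10q21.2 fell from 100% to 0. H3K27me3 rose at 5q31.2 (chr5:139380001-139410000), from 0 to 98.5 ± 1.75%, where H3K36me2 covered 100% in both control groups, 16.3 ± 23.1% in DMSO shNSD1 and 34.0 ± 48.1% in GSK126 shNSD1 cells (n = 2). It also rose at 2p11.2 (chr2:86500001-86530000), from 0 to 90.5 ± 8.51%. Limma called 1367 fallen and 102 risen H3K36me2 bins of 111163, and 215 risen and 0 fallen H3K27me3 bins of 114657 (7589 at an unadjusted p under 0.05). With the replicate number as a block limma called 50 risen and 0 fallen H3K27me3 bins (8083 unadjusted). Without the block and at equal covered length, the counts were 1801 fallen and 772 risen, and 44 risen and 51 fallen, so that H3K27me3 no longer moved one way. There limma called 2 of the 18 testable bins at 1q42.2 and 1 of 7 at 1q42.3, but not 6q24.1 or GUCA2B (adjusted p = 0.194), and no H3K27me3 island was left to test at 5q31.2 or 2p11.2. The H3K27me3 rises were 734 without DMSO shControl replicate 6 and 0 without each of DMSO shControl replicate 7, GSK126 shControl replicate 7, both DMSO shNSD1 and both GSK126 shNSD1 libraries. Without GSK126 shControl replicate 6, 467 rose and 1166 fell. Limma called 0 H3K27me3 bins with a variance trend (8014 at an unadjusted p under 0.05) and 0 among bins of intermediate mean share (5966 unadjusted). For H3K36me2 the fallen and risen counts were 803 and 54 without DMSO shControl replicate 7, 574 and 39 without GSK126 shControl replicate 7, 544 and 47 without DMSO shNSD1 replicate 6, 613 and 87 without its replicate 7, 708 and 139 without GSK126 shNSD1 replicate 6 and 2778 and 104 without its replicate 7. The H3K36me2 falls of both experiments shared 89 bins, against 51.2 for independent lists, and 13, against 18.4, at equal length. The H3K27me3 rises shared 19, against 6.02, and 2, against 0.791, at equal length.

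The covered length of H3K36me2 over both experiments was lower with NSD1 loss by a mean log2 ratio of -0.25 (exact permutation test within the 4 backgrounds, two-sided p = 0.0386, 1296 arrangements). The SMARCB1 cells carried it, at 756 ± 60.5 Mb in sgControl and 461 ± 170 Mb in sgNSD1 cells, against 731 ± 63.4 and 722 ± 5.10 Mb in GFP, 793 ± 13.5 and 707 ± 19.3 Mb in DMSO and 769 ± 71.8 and 741 ± 120 Mb in GSK126 cells. In that exact permutation test the p rose above 0.05 without GFP sgControl replicate 2 (-0.23, p = 0.0818), GFP sgNSD1 replicate 2 (-0.25, p = 0.0540), SMARCB1 sgControl replicate 1 (-0.23, p = 0.205) or 2 (-0.27, p = 0.154), SMARCB1 sgNSD1 replicate 2 (-0.15, p = 0.0664), GSK126 shControl replicate 7 (-0.23, p = 0.111), DMSO shNSD1 replicate 6 (-0.24, p = 0.0509) or GSK126 shNSD1 replicate 6 (-0.21, p = 0.123). For H3K27me3 the log2 ratio with NSD1 loss was 0.45 (exact permutation p = 0.423), but 0.01 without GSK126 shControl replicate 6, the library of 48.1 Mb, and 0.89 without GSK126 shControl replicate 7. The H3K27me3 ratio with SMARCB1 was -0.05 over both backgrounds (exact permutation p = 0.556), which moved opposite ways, from 564 to 470 Mb in sgControl and from 539 to 604 Mb in sgNSD1 cells. With stricter islands the H3K36me2 call was also lost (-0.30, exact permutation p = 0.176) and the SMARCB1 ratio turned to 0.02 (exact permutation p = 0.944). These islands were cut at 1 value of raw reads per kb, not scaled for depth. Mean density in H3K36me2 libraries ran from 41.0 (DMSO shNSD1 replicate 7) to 77.3 reads per kb (SMARCB1 sgControl replicate 1). The changed values therefore cannot tell a change of the mark from one of depth.

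Whether SMARCB1 and GSK126 removed H3K27me3 from the same places was asked last. In shControl cells GSK126 gave 0 fallen bins by limma among the 90712 bins tested in both experiments (against 7489 with SMARCB1), so the lists of calls could not be compared. Ranked by size, the 500 largest falls of each treatment shared 4 bins, against 2.76 for independent lists (Fisher's exact test, two-sided p = 0.361). At equal covered length, the 613 and 110 fallen bins among 13021 shared 4, against 5.18 (Fisher's exact p = 0.820). Neighbouring bins belong to one domain, so these p-values describe the lists only. The genes NSD1, SMARCB1, EZH2, CDKN1A and CDKN2A and the HOXA cluster were not analysed here.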

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

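The patterns below were noticed in the data and the bound for each test was set before its value was seen, while the splits with equal replicate numbers were chosen only after the results were seen.

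SMARCB1 lowered H3K27me3 in most called bins of sgControl cells and raised it in most called bins of sgNSD1 cells, and the 4966 bins (limma) that differed between these backgrounds are why this result stands out. If the SMARCB1 sgControl libraries had only yielded fewer islands, trimming every library to the same covered length should end the excess of rises, and rises then made up 43.5% of the bins called for the difference. A real change over the whole genome would give near-even shares under that trimming too, so a lower yield and an effect of NSD1 loss both stay open. A cause in a few regions, such as a changed copy number, would leave most chromosomes without the pattern, but 19 of 23 had a negative mean change in sgControl and a positive one in sgNSD1 cells, too few to exclude it by the bound set.

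H3K36me2 fell more with SMARCB1 in sgNSD1 than in sgControl cells, which stands out for the 7277 bins called by limma for the difference. The tables argue against SMARCB1 sgNSD1 replicate 2, the library with the least coverage, as the whole cause, because without it 86.2% of the bins called for the difference were still more negative. A lower island yield of whole libraries stays open, since at equal covered length the more negative bins made up 46.8%. As above, a real genome-wide loss of the mark, which may follow from NSD1 loss together with SMARCB1, would give the same outcome and cannot be excluded.

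H3K27me3 islands were nearly absent in GSK126 shControl replicate 6 (48.1 Mb) and not in replicate 7 (559 Mb). Background was read over islands whose middle lay in a bin covered in both libraries. It was 31.5 reads per kb, 140% of the 22.4 in DMSO shControl replicate 6, against 70.2% in replicate 7. This argues against a shallow ChIP library, with a limit. The 3659 GSK126 and 1156 DMSO islands of replicate 6 were not the same stretches and may reach outside these bins. Of the covered length of GSK126 shControl replicate 6, 98.9% lay inside the islands of DMSO shControl replicate 6, which span 22.0% of the genome. But so did 92.6% of replicate 7 in its own DMSO islands, so this shows only that the remaining islands may be part of the usual domains. A weaker immunoprecipitation, a stronger response to GSK126 in that culture, a difference between replicates by batch or reagent (replicate 6 H3K27me3 lists carry a tag, unexplained in the labels, that replicate 7 lists lack; the other 3 covered 667, 658 and 514 Mb) and a label error in replicate 7, whose H3K27ac library carries DMSO as its agent, may each give this and stay open, the last 2 untested.

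For NSD1 loss over both treatments, all 35 splits of the 8 libraries into groups of 4 were counted. For H3K36me2 in the doxycycline experiment only the real split called as many bins (1 of 35 splits, 6803 bins, highest other 4396). This rank does not exclude chance, because the 2 libraries of a group may not be separate cultures and would then fall together in any case. For H3K27me3 in the drug experiment it was also 1 of 35 (215 bins, highest other 20), but these libraries are paired by number, and the count went to 0 by limma without each of 6 single libraries and with a variance trend (8014 bins at an unadjusted p under 0.05). For H3K27me3 in the doxycycline experiment 2 of 35 splits called as many (3454 bins, highest other 6830), and the other was GFP against SMARCB1, a structure of the samples by design, so chance was not excluded. For H3K36me2 in the drug experiment it was also 2 of 35 (1469 bins, highest other 2353), and the other parted replicates 6 and 7, whose H3K27me3 lists also differ by a tag that the labels do not explain. With the replicate number as a block this last test called 107 risen and 1779 fallen bins by limma. Only 18 splits put 2 libraries of each replicate number on each side, too few for a share under 0.05. In the drug experiment the real one of these called 1469 H3K36me2 bins (highest other 134) and 215 H3K27me3 bins (highest other 0 by limma), and the other 17 mix shControl and shNSD1 libraries on each side.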

How the results depend on the processing

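The overlap of falls at equal covered length, the replicate block for H3K36me2 at windows and the tests of NSD1 loss within 1 treatment were chosen only after the results were seen. Counts of bins are given as Mb called by limma, and the cause of a change was not tested unless stated. Direction and side of the threshold (counts within 1.5 times) were kept in 23 of the results with 5-kb bins, 22 with stricter islands, 24 with a variance trend, 27 with the filter on mean share and 5 at equal covered length, and in all 4 covered lengths with islands of at least 2 kb. At equal covered length 11 others moved, 6 turned direction and 9 gained a call. The exceptions follow, beside the values as reported in brackets.

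With stricter islands H3K27me3 changed over 73.11 Mb (112.6) with SMARCB1 in sgControl cells, over 15.56 (34.54) with NSD1 loss in the doxycycline experiment and over 1.67 (0) with GSK126 in shControl cells. H3K36me2 changed over 5.27 (0) and 1.72 (0) with GSK126 in shControl and shNSD1 cells, 3.93 (0) for their difference and 24.58 (14.69) with NSD1 loss in the drug experiment. The log2 ratio of covered H3K27me3 with SMARCB1 became 0.0211 (-0.05), and that of H3K36me2 with NSD1 loss -0.30 (-0.25, exact permutation p 0.176 against 0.0386). For these ratios the cutoff was in raw reads per kb, so they cannot tell depth from the mark.

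Trimming to equal covered length by construction removes differences in total coverage, and with it the main direction turned for 6 results. These were H3K27me3 with SMARCB1 in sgControl (83.48 Mb) and sgNSD1 cells (83.42), their difference (35.3) and NSD1 loss in the drug experiment (0.95), and H3K36me2 with SMARCB1 in sgNSD1 cells (94.59) and its difference (65.73). H3K27me3 further gave 19.3 for NSD1 loss in the doxycycline experiment, 2.18 and 1.87 for GSK126 in shControl and shNSD1 cells and 1.94 for their difference. H3K36me2 gave 52.09 with SMARCB1 in sgControl cells, 33.69 for NSD1 loss in the doxycycline and 25.73 in the drug experiment, 2.83 and 0.83 for GSK126 and 0.6 for its difference. H3K27ac gave 2.18 and 1.77 with SMARCB1 in sgControl and sgNSD1 cells and 0.06 for the difference.

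With 5-kb bins NSD1 loss changed H3K27me3 over 20.1 Mb in the doxycycline and 3.5 in the drug experiment and H3K36me2 over 43.9 in the doxycycline experiment, and GSK126 changed H3K36me2 over 0.615 and 0.205 in shControl and shNSD1 cells. A variance trend gave 0 for H3K27me3 and 2.58 for H3K36me2 with NSD1 loss in the drug experiment, and 1.63 and 3.72 for H3K27ac with SMARCB1 in sgControl and sgNSD1 cells. The filter on mean share gave 0 by limma for H3K27me3 with NSD1 loss in the drug experiment (5966 bins at an unadjusted p under 0.05). Gains of H3K27me3 at windows that lost H3K36me2 were 16, 9.47 and 7.77 points in GFP, SMARCB1 and DMSO cells when 10 percent covered was enough, and 9.07 and 17.5 points in SMARCB1 and GSK126 cells in 5-kb windows. With the H3K27ac library of conflicting labels counted as DMSO, H3K27ac at windows that lost H3K27me3 with GSK126 turned to -0.0567 points (exact permutation p = 0.917). The falls of SMARCB1 and GSK126, 0 as called, overlapped in 4 bins among the 500 largest and in 4 at equal covered length.

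With the replicate block the difference of SMARCB1 effects came to 14.29 Mb for H3K27me3 and 27.36 for H3K36me2, and NSD1 loss in the drug experiment to 0.5 for H3K27me3. NSD1 loss in GFP cells came to 31.2 (57.74) for H3K27me3 and 50.42 (75.68) for H3K36me2, and 28 results kept their side of the threshold. For H3K27ac in the drug experiment, replicate differences correlated at 0.695 to 0.813 among the groups other than DMSO shControl, which thus deviated together. With DMSO shControl they correlated at -0.303 to -0.213, and no test within pairs was run for H3K27ac at windows. In the doxycycline experiment the correlations were -0.0242 to 0.0279 for H3K27me3 and -0.200 to 0.00480 for H3K36me2. For H3K27ac there they were 0.294 to 0.361, but -0.177 to 0.0171 with SMARCB1 sgControl, whose replicates are 1A and 2.

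Each library was left out in turn, a lone library being taken to vary like the other groups. This kept 226 values, while 77 moved, 18 gained a call, 17 lost one and 14 turned direction. Called H3K27me3 spanned 72.97 to 123.84 Mb with SMARCB1 in sgControl cells, 91.58 to 149.36 in sgNSD1 cells, 27.45 to 123.19 for the difference, 43.73 to 84.53 for NSD1 loss in GFP cells, 56.62 to 136.82 in SMARCB1 cells and 20.69 to 27.12 over both. With GSK126 it spanned 0 to 496.79 in shControl cells, 0 to 0 in shNSD1 cells and 0 to 374.16 for the difference, and with NSD1 loss 0 to 12.56 in DMSO, 0 to 381.44 in GSK126 cells and 0 to 16.33 over both. H3K36me2 in the same order spanned 56.2 to 98.92, 84.22 to 569.52, 37.1 to 533.43, 46.03 to 84.65, 95.75 to 596.69 and 43.52 to 58.32 Mb, and 0 to 23.12, 0 to 25.59, 0 to 11.78, 0 to 35.91, 0.79 to 33.67 and 5.91 to 28.82 Mb. H3K27ac spanned 0.79 to 83.56, 1.61 to 133.64 and 0 to 140.1 Mb with SMARCB1 and 0 to 10.75, 0 to 80.25 and 0 to 30.24 with GSK126, each in control cells, NSD1-loss cells and for the difference. Log2 ratios of covered length ran from -1.96 to -0.19 for H3K27me3 with GSK126, -0.07 to -0.03 with SMARCB1 and 0.01 to 0.89 with NSD1 loss, and from -0.35 to -0.15 for H3K36me2. Gains at windows ran from 10.8 to 18.4 points in GFP, 2.39 to 10.9 in SMARCB1, 3.32 to 26.8 in DMSO and 9.89 to 36.1 in GSK126 cells. At windows that lost H3K27me3, H3K36me2 rose by 2.09 to 4.15 points with GSK126 and 10.4 to 12.5 with SMARCB1, and H3K27ac changed by -0.00981 (without GSK126 shNSD1 replicate 7) to 0.507 and 1.29 to 2.52.

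Tests of NSD1 loss within 1 treatment, added after the data were seen, also changed. For H3K36me2 in DMSO (3.62 Mb) and GSK126 cells (5.32) limma called 0 bins with the variance trend (7806 and 7652 at an unadjusted p under 0.05), the filter on mean share (6587 and 5790) and the replicate block (10622 and 9651), but 7.47 and 9.26 Mb with 5-kb bins, 19.35 and 23.81 with stricter islands and 16.35 and 16.88 at equal covered length. In SMARCB1 cells H3K27me3 (90.35) came to 58.12 with stricter islands and 50.03 at equal covered length, and H3K36me2 (182.23) to 90.85 at equal covered length. H3K27me3 in DMSO and GSK126 cells (0) came to 2.02 and 2.07 at equal covered length.

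The planned gene lists and their replicate block were not run, because too few listed genes had a position. Total reads are not in the lists, so a region that lost its island in a shallow library cannot be told from a region that lost the mark.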

Other observations

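The regions and chromosomes in this part were chosen after their values were seen. At 1p33 (chr1:46910001-46960000) the 3 marks followed different factors. H3K36me2 covered 8% in GFP sgControl cells, 98.2 ± 0.283% in GFP sgNSD1, 97.6 ± 0.566% in SMARCB1 sgControl and 22.8 ± 2.83% in SMARCB1 sgNSD1 cells (n = 2 each), so that either change alone went with a high level and both together with a low one. H3K27me3 covered 5.00 ± 0.283%, 43.6 ± 0.566%, 10.8% and 83.4 ± 4.24% in the same order, and H3K27ac 79.6 ± 1.69%, 79.9 ± 3.23%, 13.3 ± 4.79% and 2.15 ± 1.78%. Limma still called 4 of its 5 bins for the H3K36me2 rise with NSD1 loss in GFP cells at equal covered length.

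At 8q22.1 (chr8:97200001-97240000) H3K27me3 went against the genome-wide rise with NSD1 loss in SMARCB1 cells, from 96.5 ± 1.41% to 0, while it covered 90.3 ± 10.3% and 97.8 ± 0.354% in GFP sgControl and GFP sgNSD1 cells (n = 2 each). No H3K36me2 island and no H3K27ac peak lay there in any of the 4 groups, and all 4 bins were called at equal covered length. At 10q22.1 (chr10:73400001-73500000) H3K27me3 rose with NSD1 loss in SMARCB1 cells from 13.1 ± 1.56% to 75.8 ± 3.11%, against 0 and 9.80 ± 0.283% in GFP cells. H3K36me2 there covered 81.5 ± 4.10% and 9.90 ± 9.19% in SMARCB1 cells and 98.6 ± 0.849% and 88.1 ± 2.97% in GFP cells. Limma called 5 of its 10 bins at equal covered length.

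The X chromosome stood at the end of the range over the 23 chromosomes for several comparisons of H3K36me2. With SMARCB1 its mean change was 17.9 points in sgControl cells, the highest, with 189 bins risen and 17 fallen of 1799 by limma, and -31.8 points in sgNSD1 cells, the lowest, with 0 risen and 421 fallen. With NSD1 loss it was 16 points in GFP cells, the highest, and -33.6 points in SMARCB1 cells, the lowest. H3K27me3 on X changed by 14.7 points with NSD1 loss in GFP cells, with 158 bins risen and 2 fallen of 1557, where chromosome 8 had the lowest mean, -9.94 points. With SMARCB1 in sgNSD1 cells it changed by -12.1 points, the lowest, while 20 of 23 chromosomes were above 0. Both marks thus moved the same way on X in these comparisons. They moved opposite ways with NSD1 loss in SMARCB1 cells, where H3K27me3 on X changed by 5.95 points, the lowest. The cause was not tested. These means are of islands as deposited and were not computed at equal covered length.

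The mean change of H3K27ac with SMARCB1 was above 0 on all 23 chromosomes in sgControl cells (0.497 to 8.19 points) and below 0 on all 23 in sgNSD1 cells (-13.5 to -2.00 points), although the called bins mostly fell in both and limma called no bin for the difference (3098 at an unadjusted p under 0.05). The second value sets the 2 SMARCB1 sgNSD1 libraries, with 39.3 (replicate 1) and 152 Mb of peaks (replicate 2), against GFP sgNSD1 libraries of 121 and 149 Mb. Without SMARCB1 sgNSD1 replicate 1 the called bins of sgNSD1 cells mostly rose, so the fall in the mean may rest on that library.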
